A study of Mus musculus with 12 samples.

How the data were processed

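RNA of E14 mouse embryonic stem cells had been extracted with Trizol, and 100 ng of total RNA per sample had been labelled with an Affymetrix whole-transcript sense assay, per the labels' protocols. The deposited values are log2 signals per transcript cluster, one column per array. RMA, limma and R 3.1.1 are named in the submitters' processing notes, with no role or order given. The range of the values, from 0.567 to 13.8, and the near-equal medians of the arrays are those of log2 values normalized between arrays. No scanner files were used here, so the background correction and normalization could not be checked against raw intensities. Normalization between arrays takes out shifts that affect most genes, so a global change of RNA content would not appear in these values.

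The 12 arrays were grouped by the labels into shCT and shLOXL2, each without RA (day 0) and with RA (day 1), with 3 arrays per group. Clusters were named through the platform annotation, and symbols were updated through the gene identifiers of a RefSeq gene table. Of 41345 clusters, 23521 had 1 gene, 1814 had several and 16010 were unnamed here. The RefSeq table matched 23328 of the clusters with 1 gene and missed 193. A gene with several clusters (1082 genes) was represented by the brightest, and none of them had clusters called in opposite directions for RA on average. The table of 22180 genes held 18964 protein-coding genes. Clusters with several genes or none stayed out of it. No genome was used, so no positions are given.

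Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on the deposited log2 values, without a further filter. One fit over all 12 arrays had 1 mean per group and shared the spread between groups. There were 7 contrasts: RA in each construct, knockdown in each RA state, the difference between the RA responses, and the averages of knockdown and of RA. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors of log2 changes are standard errors of this fit, with 3 arrays per group. Single values were tested by exact permutation: splits of 3 against 3 cannot give a two-sided p below 0.1, and the 400 relabellings of constructs within RA states were enumerated in full.

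Before the data were examined, 21 gene lists, the tests, the rule for named genes and the other ways of processing were fixed. The lists were tested with limma's camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. Fry tests whether the genes of a list move on balance one way and does not compare them with other genes. Adjusted p-values of lists cover the 21 lists of a contrast. The rule for named genes took, per contrast, the 6 largest rises and the 6 largest falls past the threshold, for comparisons of 2 groups only where the arrays did not overlap. It left out predicted and numbered gene symbols, microRNAs, small nucleolar RNAs and receptor families for odours and pheromones. It added up to 3 members with the smallest p per list, the 5 smallest p-values where no gene passed, and Loxl2 and Taf10 always. The symbols left out apply to the rises and falls, not to the smallest p-values. RA was read as retinoic acid, which the labels give only as RA.

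The fit was tested on simulated data made from the real means, spreads and axis of variation, with 200 of 22180 genes changed by known amounts. For RA in shCT it recovered 13.4% of changes of 0.5 log2 units, 74.3% of changes of 1 and 98.5% of changes of 2, with 0.642% of calls false. For knockdown on average it recovered 43.9%, 92.2% and 99.7%. The simulated axis could not shift the mean of a group, and the simulated arrays were not paired by number. The share of false calls therefore does not cover such shifts. On the real arrays, 1 other relabelling of the constructs gave 2179 genes for knockdown on average. The list test called a list of 20 genes shifted by 0.5 log2 units in 20 of 20 simulations and 1 of 400 unshifted lists. Its simulations had independent noise for each gene and no axis, so these counts hold only for uncorrelated genes. The estimated correlation within the real lists reached 0.624.

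The other ways of processing fixed in advance were the replicate number as a block, a variance trend with robust moderation, leaving out genes dimmer than the median, a second quantile normalization, centring arrays on their medians, the mean of a gene's clusters, only the groups compared, array weights, a fold of at least 1.5, all transcript clusters, and leaving out each array. After seeing the data, 4 were added: the axis within groups as a covariate, a fit without the 4 arrays that lay high on it, and a fixed or random block for each construct and replicate number. The random block used limma's duplicateCorrelation (consensus correlation 0.323). The fixed block serves the RA contrasts only, since construct and block cannot be separated. The numbers come from the labels, which name no pairing, so whether they pair arrays was checked by the correlation of deviations from the group means. Between shLOXL2 without and with RA it was 0.558, 0.248 and 0.216 for numbers 1 to 3, all over 0.1. In shCT it was 0.363, 0.0394 and 0.631, with 1 pair under 0.1 but also the highest pair of both constructs. These values do not set the constructs apart. Counts with the arrays paired by number are therefore given for both, beside the main fit. Figures were drawn with matplotlib 3.10.9.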

Results

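The series profiled E14 cells, a mouse embryonic stem cell line, that carried either a control short hairpin RNA (shCT) or a hairpin against LOXL2 (shLOXL2), a member of the lysyl oxidase family. Cells of each kind were sampled without RA (retinoic acid) at day 0 and after RA at day 1, which gave 4 groups of 3 arrays each and 12 arrays in all. No group without RA was sampled at day 1, so RA cannot be told apart from a day of culture. A change with RA below covers both. The title of the series places the question in LOXL2-dependent genes during differentiation induced by RA. Each array gave a log2 signal for 41345 transcript clusters, and 22180 named genes were tested. Array medians lay between 4.58 and 4.68 on the log2 scale, and pairs of arrays correlated at 0.939 to 0.985 across clusters. For these arrays the precision is limited by their number. Nothing in the labels says whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

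The knocked-down gene was examined first, since it checks the labels. Both clusters that cover Loxl2 are also annotated to Gm21451, a predicted gene, so they stayed out of the gene table and their signal cannot be assigned to Loxl2 alone. In cluster 17301634 the mean log2 signal was 5.50 ± 0.295 (SD, n = 3) in shCT and 4.94 ± 0.140 in shLOXL2 without RA, and 6.09 ± 0.368 against 5.18 ± 0.105 with RA. Averaged over both RA states, the shLOXL2 signal was 60.0% of control, a log2 difference of -0.74 ± 0.14 (SE). Exact relabelling of the constructs within each RA state gave a two-sided p of 0.005, the smallest that the relabellings allow, while the limma adjusted p over all clusters was 0.28. In cluster 17301670 the average was 65.0% of control (log2 difference -0.62 ± 0.16, exact p = 0.03, limma adjusted p = 0.543). Were arrays of the same construct and number 1 unit, the units would be 3 against 3 and no exact p could go below 0.1. No background level was set here and the shLOXL2 means lay near the array medians, so these percentages are upper bounds of the remaining level where part of the signal is background. That cluster stood at 47.2% of control with RA and at 89.6% without RA, and the latter difference changed sign without replicate 3 of the shCT group without RA (log2 0.015). The difference between those RA states did not pass the exact test (p = 0.11). Both clusters annotated to Taf10, a subunit of the general transcription factor TFIID, are shared with Ilk. Their knockdown differences on average were -0.07 ± 0.09 and -0.07 ± 0.10 on the log2 scale, with a limma adjusted p of 1.

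**Figure D1:**
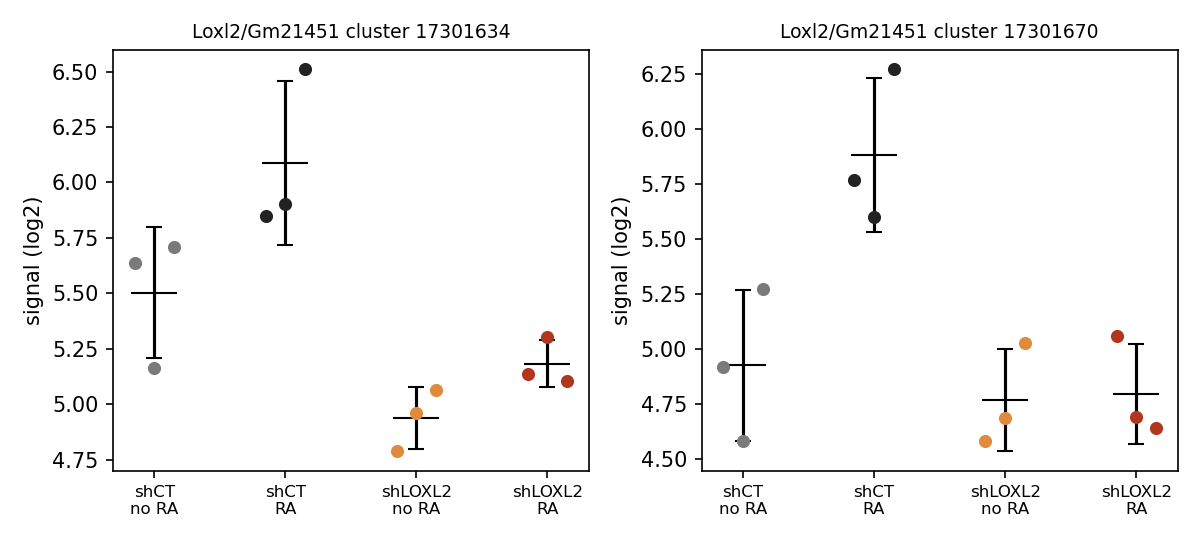
Log2 signal of both clusters annotated to Loxl2 and Gm21451, by group. Points are single arrays, horizontal marks are means and bars are 1 SD (n = 3); in cluster 17301634 all 3 shLOXL2 arrays lay below the 3 shCT arrays in each RA state.

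In control cells, genes of retinoid signalling and the Hox clusters were higher after 1 day with RA, and genes of the pluripotent state were lower. The largest rises were those of Stra8, a meiotic gatekeeper induced by retinoic acid (log2 change 5.29 ± 0.15, SE), and Hoxb1 (4.43 ± 0.22). Cyp26a1, which degrades retinoic acid, rose by 4.09 ± 0.16 and Hoxa5 by 3.84 ± 0.19. Aqp3, a water and glycerol channel, rose by 3.17 ± 0.16, and Meis2, a homeodomain cofactor of Hox proteins, by 3.02 ± 0.22. The largest falls were those of Klk1, a kallikrein protease (-2.46 ± 0.18), and Slc27a2, a fatty acid transporter (-2.39 ± 0.18). Mycn fell by 2.37 ± 0.17, the Wnt effector Lef1 by 2.22 ± 0.22, the immediate early gene Egr1 by 2.12 ± 0.15 and the dynein gene Dnah8 by 2.08 ± 0.17. Adjusted p-values of these 12 genes were at most 4.18e-05. The shCT means without RA of Stra8 (4.30), Cyp26a1 (4.2) and Hoxa5 (3.725), and that of Klk1 with RA (3.19), lay below the array medians. No background level was set here. Where part of these signals is background, the changes of these genes are lower bounds and their order is not firm. In all, 943 of 22180 genes passed the limma threshold, of which 480 rose and 463 fell, and 252 changed by over 1 log2 unit. Centring each array on its median gave 1206 genes, of which only 27.9% rose, against 50.9% before. That centring moved the median change of all genes to -0.10, so the balance of rises and falls depended on the scaling. Without replicate 2 of shCT without RA 483 genes passed, and without replicates 1, 2 and 3 of shCT with RA 512, 555 and 561. With the arrays paired by number within the construct, an alternative chosen after seeing the data, 1800 passed, 937 upward and 863 downward.

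The gene lists, fixed before the data were examined, were compared next in control cells. Of 23 Hox genes measured, 17 rose and none fell (19 rose when adjusted over the list alone), led by Hoxb1, Hoxa5 and Hoxb2 (2.83 ± 0.15). Of 21 direct retinoic acid targets, 14 rose (15 adjusted over the list alone), among them Dhrs3, a retinaldehyde reductase (2.96 ± 0.15). With an estimated correlation between genes, the adjusted p of limma's camera test was 0.00493 for the Hox list and 0.0003 for the target list. Among 19 genes of naive pluripotency 7 fell and 1 rose (11 and 1 adjusted over the list alone). The nuclear receptor Nr5a2 fell by 1.41 ± 0.13 and Nr0b1 by 1.11 ± 0.13, while Tbx3 rose by 1.15 ± 0.16. Among 15 genes of general pluripotency 4 fell and 1 rose (6 and 1 adjusted over the list alone), with Zscan10 at -1.05 ± 0.13 beside Mycn. Both pluripotency lists kept their call with an estimated correlation (adjusted p = 0.0248 and 0.00593). Of 15 genes of the formative and primed epiblast 5 fell (7 adjusted over the list alone), including Otx2 (-1.57 ± 0.14) and the DNA methyltransferase Dnmt3b (-1.44 ± 0.17). The list lost its call with an estimated correlation (adjusted p = 0.12).

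Few lineage markers passed the threshold in control cells. Of 18 mesoderm and primitive streak genes 2 rose, Lefty1, a Nodal antagonist (2.13 ± 0.25), and Wnt3 (0.65 ± 0.13), the same count as adjusted over the list alone. Of 21 neural progenitor genes 3 rose, including the RNA-binding protein gene Msi1 (0.90 ± 0.13) and Sox1 (1.06 ± 0.22), and 5 rose and 2 fell when adjusted over the list alone. Of 20 genes of primitive and extraembryonic endoderm, Gata6 rose by 1.27 ± 0.24 and Apoe fell by 0.73 ± 0.16 (1 rose and 2 fell when adjusted over the list alone). No trophectoderm gene among 16 passed, and Cdx2 stood at 0.62 ± 0.19. Camera with the preset correlation called the mesoderm list (adjusted p = 0.00364) and the trophectoderm list (adjusted p = 0.00523) upward, and with an estimated correlation neither passed (adjusted p = 0.211 for each). The neural and endoderm lists were not called (adjusted p = 0.0546 and 0.699). Of 14 epithelial genes 5 fell and 1 rose (6 and 1 adjusted over the list alone). The transcription factor Grhl2 fell by 1.57 ± 0.15 and the splicing regulator Esrp1 by 1.46 ± 0.18, while the desmosomal gene Dsp rose by 1.21 ± 0.16 (list adjusted p = 0.201 with an estimated correlation). Of 11 mesenchymal genes only Tgfb1 passed, at -0.71 ± 0.16 (1 rose and 1 fell when adjusted over the list alone), and the list was not called (adjusted p = 0.389). Several of these calls were lost when 1 array was left out, while the changes kept their direction. With 1 array left out they ran from 0.59 to 0.74 for Wnt3, 0.82 to 1.30 for Sox1 and 1.07 to 1.57 for Gata6. For Apoe they ran from -0.81 to -0.67 and for Tgfb1 from -0.76 to -0.65. Without replicate 1 of shCT with RA the adjusted p was 0.0593 for Wnt3, 0.0533 for Sox1, 0.0506 for Gata6, 0.0763 for Apoe and 0.0915 for Tgfb1. Without replicate 2 of shCT without RA it was 0.0693 for Wnt3, 0.0557 for Sox1, 0.0509 for Gata6 and 0.0985 for Tgfb1. Without replicate 2 of shCT with RA it was 0.0688 for Wnt3, 0.0606 for Sox1 and 0.0789 for Apoe. Apoe also stood at 0.0584 without replicate 1 of shCT without RA, and Tgfb1 at 0.0604 without replicate 3 of shCT with RA.

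In shLOXL2 cells RA changed 768 genes past the limma threshold, 455 upward and 313 downward. With the arrays paired by number within the construct, an alternative chosen after seeing the data, 1624 passed, 985 upward and 639 downward. Centring on array medians left 47.1% of calls upward, against 59.2%. Without replicates 2 and 3 of shLOXL2 without RA 461 and 488 genes passed, and without replicates 2 and 3 of shLOXL2 with RA 511 and 444. The largest rises were again those of Stra8 (4.88 ± 0.15), Cyp26a1 (4.29 ± 0.16), Hoxa5 (3.89 ± 0.19) and Hoxb1 (3.71 ± 0.22), followed by Aqp3 (2.92 ± 0.16) and Dhrs3 (2.70 ± 0.15). The largest falls were those of Klk1 (-3.38 ± 0.18), Slc27a2 (-2.33 ± 0.18) and Mycn (-2.11 ± 0.17). They were followed by the transglutaminase gene Tgm3 (-1.99 ± 0.19), the pluripotency factor Foxd3 (-1.93 ± 0.16) and Lef1 (-1.90 ± 0.22). The shLOXL2 means without RA of Stra8, Cyp26a1, Hoxa5 and Dhrs3, and that of Klk1 with RA (2.89), lay below the array medians. The changes of these genes are lower bounds too where part of the signal is background. Of the Hox genes 15 rose, and of the direct targets 14 rose, the same counts as when adjusted over the list alone. In the naive list 7 fell and 1 rose (9 and 1 adjusted over the list alone), and in the general pluripotency list 5 fell and 1 rose (8 and 1 adjusted over the list alone). These 4 lists were called in shLOXL2 cells with an estimated correlation too (adjusted p = 0.00659, 0.000506, 0.0234 and 0.00433). In the formative list 5 of 15 genes fell (6 adjusted over the list alone, list adjusted p = 0.166 with an estimated correlation).

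The RA responses of both constructs ran together. Of the genes that rose, 312 were called in both constructs, against 9.85 for independent lists. Of those that fell, 245 were called in both, against 6.53, and none was called in opposite directions. These comparisons share no arrays, but they share 1 estimate of the spread per gene. Genes with a small spread were favoured in both, so the numbers for independent lists are too low a yardstick. Across genes, which are not independent replicates, the RA changes correlated at r = 0.736 (rho = 0.551). Over the 1224 genes that rose on average of both constructs, the median change was 0.55 in shCT and 0.56 in shLOXL2 (exact two-sided p of the difference = 0.925). Over the 1065 genes that fell, it was -0.53 and -0.48 (exact p = 0.295). On average of both constructs 2289 genes passed the threshold, 53.5% of them upward, or 32.9% after centring on array medians. Besides the genes already named, Hmces, a protector of abasic DNA sites, fell by 1.91 ± 0.11 on this average.

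**Figure D2:**
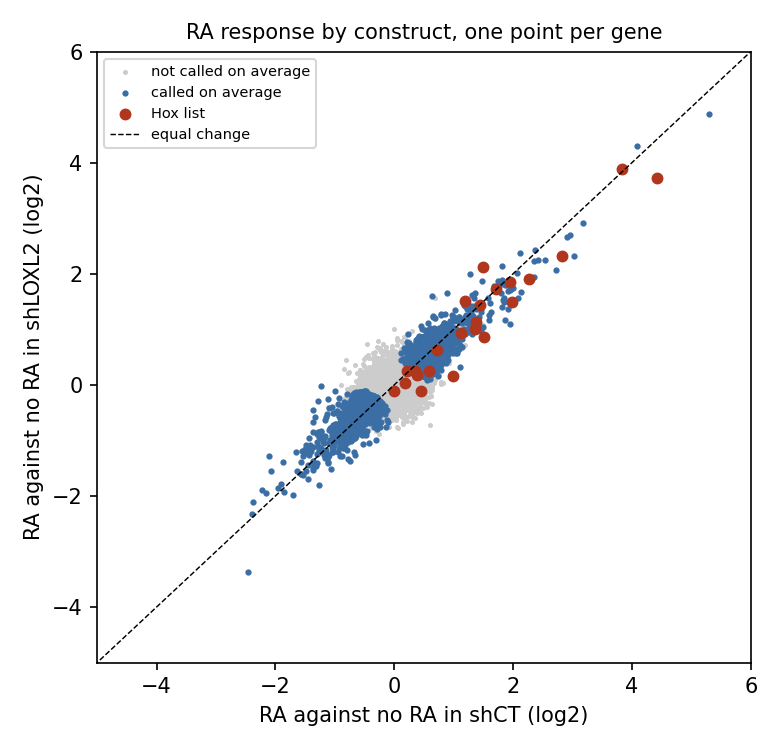
RA response of each gene, as log2 change in shCT (x axis) and in shLOXL2 (y axis), with the line of equal change. Blue points are the 2289 genes called on average, red points the 23 Hox genes and grey points all others; the responses correlated at r = 0.736.

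No gene passed the threshold for a different RA response in shLOXL2 than in shCT cells. The limma fit gave 652 genes at an unadjusted p under 0.05, below the 1109 expected by chance. With arrays paired by number within constructs, chosen after seeing the data, it gave 1228 (fixed block) and 1331 (random block). The side of the chance number therefore depended on the pairing, while the count past the threshold stayed at 0. The smallest p-values belonged to Pate1 (-0.95 ± 0.20), Gm15080 (1.06 ± 0.22), Aym1 (-0.95 ± 0.21), the kinase gene Btk (-0.77 ± 0.18) and the Hippo pathway factor Tead3 (-0.82 ± 0.19), all with an adjusted p of 1. As a list, the Hox genes had a lower RA response in shLOXL2 cells, with 17 of 23 lower and a median difference of -0.20. Hoxa6 differed by -0.65 ± 0.20, Hoxc5 by -0.83 ± 0.29 and Hoxb2 by -0.51 ± 0.21, none past the threshold. Camera called the list with the preset correlation (adjusted p = 0.00119) and not with an estimated one (adjusted p = 0.513), and exact relabelling of the constructs gave a two-sided p of 0.155. In simulated data with known changes, this comparison recovered 0% of differences of 0.5 log2 units, 33.4% of differences of 1 and 90.6% of differences of 2.

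LOXL2 knockdown changed no gene past the limma threshold within either RA state. Without RA, 1037 genes had an unadjusted p under 0.05, and with RA 1100, against 1109 expected by chance. Among the alternatives chosen after seeing the data, the fit without the 4 arrays high on the axis gave 1881 and 1615. The axis as a covariate gave 2130 and 2363, and the random block 981 and 1043. The comparison with chance therefore depended on the fit. Without RA the smallest p-values belonged to the kinase gene Map4k4 (-0.75 ± 0.11, adjusted p = 0.167), Egr1 (-0.98 ± 0.15, 0.167), Tbc1d5 (-0.72 ± 0.12, 0.27), Robo4 (0.88 ± 0.15, 0.27) and Gm15080 (-0.88 ± 0.16, 0.27). With RA they belonged to the Hedgehog receptor gene Ptch1 (-0.87 ± 0.13, adjusted p = 0.209), Erbb3 (0.76 ± 0.12, 0.318), Mypn (0.69 ± 0.12, 0.318), Mpc1 (1.17 ± 0.21, 0.318) and Rad51c (-0.77 ± 0.14, 0.318). Weighting arrays by their estimated quality gave 2875 genes without RA and 9 with RA. Those weights spanned 0.332 to 6.26, and replicate 2 of the shCT group without RA held the highest; with the same weights another split of the 6 arrays without RA gave 1820 genes. Camera with the preset correlation called 3 lists without RA, hypoxia response, endoderm and p53 targets, all lower, and with an estimated correlation none (adjusted p = 0.862, 0.862 and 0.351). With RA it called 11 of 21 lists, and with an estimated correlation none, the lowest being p53 targets (adjusted p = 0.0646). The simulated comparison without RA recovered 75.5% of changes of 1 log2 unit and 11.9% of changes of 0.5.

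Averaged over both RA states, 12 genes passed the limma threshold for LOXL2 knockdown, 8 upward and 4 downward (66.7% upward). After a further quantile normalization 18 passed, 8 upward and 10 downward (44.4% upward), and after centring on array medians 14, 10 upward and 4 downward (71.4%). The largest rise was that of Mpc1, a subunit of the mitochondrial pyruvate carrier (1.03 ± 0.15). Slc25a20, the mitochondrial carnitine-acylcarnitine carrier, rose by 0.77 ± 0.11, Robo4 by 0.76 ± 0.11 and Zyg11a by 0.71 ± 0.09. Erbb3, a receptor of the EGF receptor family, rose by 0.65 ± 0.09, and the orphan receptor gene Gpr160 by 0.60 ± 0.09. Rad51c, which acts in homologous recombination, fell by 0.77 ± 0.10, Ptch1 by 0.67 ± 0.09, Tbc1d5 by 0.63 ± 0.08 and Map4k4 by 0.60 ± 0.08. The adjusted p-values of these 10 genes were 0.0167 or 0.0172. Mypn and Gm364 fell outside the rule for named genes on this average and are named after their values were seen, at 0.53 ± 0.08 and 0.81 ± 0.11. The count was 0 when any of 7 single arrays was left out, namely each shCT array with RA and replicates 2 and 3 of shLOXL2 in both RA states. Without replicate 1 of shLOXL2 without RA it was 19. Within constructs, arrays with the same number with and without RA tended to deviate together, and with a random block for each construct and number, an alternative chosen after seeing the data, none of the 12 passed (limma, 925 genes at an unadjusted p under 0.05). The changes themselves stayed equal with this block and only their errors grew. The adjusted p of the 10 genes named by the rule was then 0.0574 to 0.0798, so these calls rest on treating the 6 arrays of a construct as independent. Tbc1d5 did not pass when its clusters were averaged (-0.24, adjusted p = 0.553).

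Several lists were called for knockdown on average by camera with the preset correlation, although no member passed the threshold over all genes. Hypoxia response genes were lower in 14 of 17 cases (median -0.16), with 6 lower past the threshold adjusted over the list alone, among them Pgk1, a glycolytic enzyme gene (-0.35 ± 0.08). The list's adjusted p was 0.651 with an estimated correlation. It was 0.626 at the preset one without the 4 arrays, 1 of each group, that lay highest on the axis within groups. Germline genes were higher in 11 of 14 cases (median 0.21), with 4 past the threshold adjusted over the list alone, including Taf7l (0.74 ± 0.15), and an adjusted p of 0.366 with an estimated correlation and 0.0801 without those 4 arrays. The p53 target list was lower in 13 of 15 genes (median -0.24), led by Plk2 (-0.36 ± 0.10) and Zmat3 (-0.25 ± 0.09). It passed with an estimated correlation (adjusted p = 0.0397) and by fry (adjusted p = 0.0172). Both tests took all arrays as independent, and lists were not tested with the random block. Exact relabelling gave an unadjusted p of 0.025, treating all arrays as independent, and its smallest p of 0.005 is too large for 1 list alone to pass after adjustment over 21 lists. The lists of endoderm, Hox and 2-cell-like genes (preset adjusted p = 0.000172, 0.0127 and 0.0203) each had an adjusted p of 0.651 with an estimated correlation. Without the 4 arrays the 2-cell-like list turned direction (adjusted p = 0.626). The knockdown changes without and with RA correlated at r = 0.235 across genes (rho = 0.195), and 64 of 400 exact relabellings gave a correlation as high (one-sided p = 0.16). With 1 array left out r ran from 0.077 to 0.274. Without dim genes it was 0.477 (one-sided exact p = 0.13).

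The arrays also differed within groups. A single axis held 49.4% of the variance within groups, and the next component held 10.7%. The 4 arrays highest on it were replicate 3 of both shCT groups and replicate 1 of both shLOXL2 groups. Their deviations correlated with each other at 0.386 to 0.631. The farthest out was replicate 1 of shCT without RA, at the low end (score -40.2, against at most 32.6 among the 4). The other 8 arrays were therefore not alike on the axis. Genes of small RNAs were lower on these 4 arrays, with a median loading of -0.38 over 86 genes, and genes of the endoderm list had a median loading of -0.34. The 2-cell-like list had a median loading of 0.35 and the germline list one of 0.18, so the genes of these lists also differed between arrays of the same group. A loading of 1 corresponded to 0.948 log2 units between the 4 arrays and the other 8. Without the 4 arrays, an alternative chosen after seeing the data, RA changed 805 genes in shCT and 695 in shLOXL2, knockdown changed 0 genes within either RA state, and 37 genes passed for knockdown on average. In that fit Robo4 (adjusted p = 0.066), Ptch1 (0.0678), Tbc1d5 (0.0704) and Map4k4 (0.0617) did not pass.

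**Figure D3:**
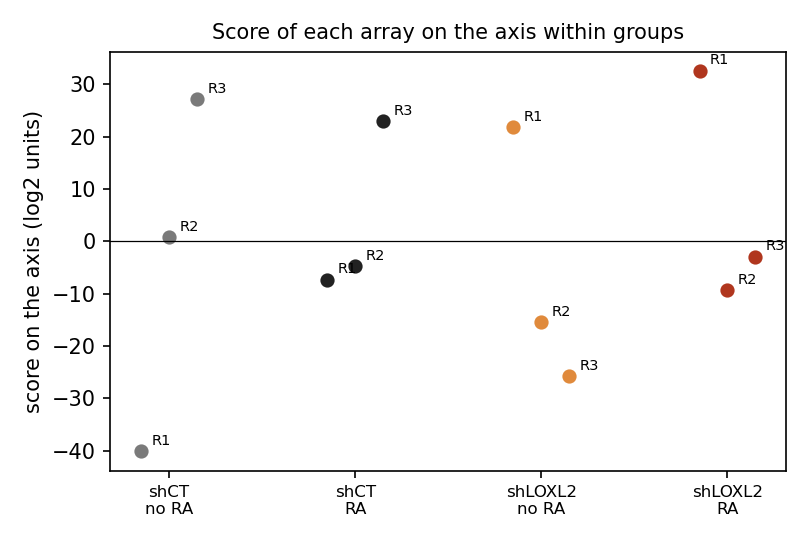
Score of each array on the main axis of variation within groups, a sum of log2 deviations over genes weighted by their part in the axis, by group, with the replicate number beside each point. The highest array of each group scored between 21.9 and 32.6, and the array farthest out, replicate 1 of shCT without RA, scored -40.2.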

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

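The tests of replicate number, of construct and number together, and of short RNA as sources of the axis within groups were chosen after the axis was seen, as were the fits with the axis as a covariate, without the 4 arrays and with a random block. A list difference between constructs, or a signal outside the gene table, brought the results of this part here.

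In 6 lists, camera with the preset correlation found an RA response that differed between shLOXL2 and shCT. The median difference was -0.20 for the Hox genes, -0.17 for direct retinoic acid targets, -0.14 for neural progenitor genes and -0.14 for mesoderm genes. It was -0.0895 for fibroblast and feeder genes and 0.15 for TFIID subunits. With an estimated correlation the adjusted p of each was 0.513 or 0.524. Outside the gene table, 335 transcript clusters with several genes or none changed with RA on average, 139 upward and 196 downward.

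The lower RA induction of the Hox genes in shLOXL2 cells was weighed against 3 explanations. The axis within groups predicted 9.88% of the median difference, which argues against the axis as its source. A smaller response of all strongly induced genes was left undecided: the median difference over the average response was -5.78% for the other 128 such genes and -17.3% for 14 Hox genes, so the former was 33.4% of the latter. The response was lower in shLOXL2 for 78 of the 128 other genes and for 9 of the 14 Hox genes. By these shares the Hox genes hardly stood apart. Chance assignment of arrays to constructs stays open, with an exact p of 0.155. A hypothesis of LOXL2 acting in Hox induction is therefore untested beyond chance here.

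For the 12 genes that changed with knockdown on average, the axis predicted a mean of -0.083% of their changes (-0.25% to 0.096% for single genes; the mean axis scores of the constructs differed by 0.362 while arrays of 1 group differed by up to 67.4), which argues against the axis as the source. Among 100 of the 200 distinct relabellings of constructs within RA states, 4 gave at least 12 genes, the real one included, a share under 0.05 but too near it to exclude chance firmly. This share treats all arrays as independent. Were arrays of the same construct and number 1 unit, no share could go below 0.1. The highest other relabelling gave 2179 genes, and all 3 others placed at least 3 of the 4 arrays that lay high on the axis under 1 construct. Of the 99 other relabellings drawn for the difference between RA responses, 60 did so too. With a placement that common, 3 relabellings are too few to trace their counts to the axis. With the axis as a covariate the count was 136, and 22 of 100 relabellings gave as many (highest other 3851), so chance is not excluded for that count. All 21 other relabellings with as many placed at least 3 of the 4 arrays under 1 construct. High counts of the relabellings in that fit therefore went with this placement. With a random block for each construct and number the count was 0, while the changes themselves stayed equal and only their errors grew. This loss of calls cannot decide whether a batch or culture shared by these arrays was their source, which stays open. An effect of LOXL2 loss and an off-target effect of the hairpin were not tested against each other.

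The axis within groups, on which 1 array of each group lay high, was set against 4 sources. Arrays with the same replicate number had a mean correlation of deviations of -0.049, which argues against a batch shared by all arrays of a number. Arrays of the same construct and number had a mean of 0.343, as high in 2 of 36 numberings, so a batch or culture shared by these arrays stays open. After a further quantile normalization the axis still held 48.0% of the variance within groups. This argues only against differences left in the array-wide distribution of values. Such a step equalizes these distributions and cannot remove differences that depend on the gene or probe. Genes of small RNAs had a median loading of -0.38 against -0.01 for matched lists of protein-coding genes. This leaves open a difference in the recovery or labelling of short RNA, a hypothesis formed on these data. Endoderm genes (-0.34 against -0.04 for matched lists) and 2-cell-like genes (0.35 against -0.08) lay about as far out. The axis was therefore not particular to genes of small RNAs.

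Other groupings of the arrays were counted for the remaining results. For RA in shCT, 1 of 10 splits of the 6 arrays gave at least the real 943 genes and the highest other gave 0. For RA in shLOXL2, 1 of 10 gave at least 768 and the highest other gave 0. For knockdown without RA, where the real count was 0 and all 10 splits gave as many, the highest other gave 563. For knockdown with RA all 10 gave 0. Splits of 3 against 3 are too few for a share under 0.05. With array weights, 1 of 10 splits gave at least the 2875 genes of knockdown without RA, and the highest other gave 1820. With array weights 9 of 100 relabellings gave at least the 1002 genes of knockdown on average (highest other 4460), so chance is not excluded there. For RA on average, only the real one of 100 relabellings gave 2289 genes, the smallest share possible, and the highest other gave 418. This argues against chance where the arrays are independent, which the labels do not say. For the difference between RA responses the real count was 0, so that all 100 relabellings gave as many by construction and the share says nothing about chance. The highest other gave 2415, a number that points to a structure of the samples whose source was not tested for this comparison.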

How the results depend on the processing

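The fits with the axis as a covariate, without the 4 arrays and with a block within constructs were chosen after seeing the data. The signal of these arrays was not set against a background level here. No alternative gave a gene with a different RA response by construct, and the Loxl2 level kept its direction and stayed short of the threshold in all alternatives run. With array weights the counts were 5224 for RA in shCT, 2663 for RA in shLOXL2, 5975 for RA on average, 2875 and 9 for knockdown without and with RA, and 1002 for knockdown on average. These weights leaned on single arrays, with the highest weight 18.9 times the lowest. With the axis as a covariate the same counts were 2474, 2212, 4584, 22, 9 and 136; the changes themselves stay equal by construction and only the residual spread falls. Knockdown on average gave 22 genes with a variance trend, 27 without dim genes (fewer genes tested), 37 without the 4 arrays and 1 over all clusters (more features tested). RA in shCT gave 599 genes with only the groups compared, and RA on average gave 892 at a fold of at least 1.5, a narrower criterion.

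Leaving out 1 array at a time gave 483 to 1049 genes for RA in shCT, with the lowest without replicate 2 of shCT without RA. It gave 444 to 916 for RA in shLOXL2, lowest without replicate 3 of shLOXL2 with RA, and 0 to 19 for knockdown on average. The causes were not tested. The correlation of knockdown changes was 0.477 without dim genes and between 0.077 and 0.274 with 1 array left out. Calls of lists over 5 contrasts fell from 39 to 8 with an estimated correlation and to 19 with fry.

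With the replicate number as a block, knockdown on average gave 1 gene in place of 12, and the RA counts were 740, 658 and 1997. Over all 4 groups the numbers did not pair the arrays: 6 of 18 pairs with the same number had deviations correlated over 0.1, and 0 arrays correlated best with their own number in all other groups. With a fixed block for each construct and number the RA counts were 1800 in shCT, 1624 in shLOXL2 and 3677 on average, and with a random block 2047, 1675 and 3871, while knockdown on average gave 0; among named genes these blocks changed no call for RA. Lists were tested with the fixed block only, which changed 1 call, that of fibroblast genes for RA in shCT (adjusted p = 0.0569). The split of knockdown calls on average was 44.4% upward after quantile normalization, against 66.7%.

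The knockdown difference of Loxl2 cluster 17301670 without RA changed sign with array weights (0.080), without the 4 arrays (0.11) and without replicate 3 of shCT without RA; leaving out 1 array gave -0.33 to 0.015. The direction of 4 list results turned, none of them past the threshold after turning. Without the 4 arrays these were 2-cell-like genes with RA and hypoxia genes with RA (adjusted p = 0.370 each) and 2-cell-like genes on average (0.626). With 1 array left out the adjusted p ran from 1.39e-05 to 0.723 for endoderm genes without RA (turned without replicate 1 of shCT without RA), from 0.000181 to 0.990 for 2-cell-like genes with RA (turned without replicate 1 of shLOXL2 with RA) and from 2.95e-05 to 0.662 for hypoxia genes with RA (turned without replicate 3 of shCT with RA). Of 1516 values of named genes under alternatives, 1435 kept direction and side of the threshold, 51 lost the call, 28 gained it and 2 turned. Of 1620 values with 1 array left out, 1467 kept both, 152 lost the call and 1 turned. For lists, 102 of 384 values under alternatives and 79 of 540 with 1 array left out lost the call, and 3 of each turned.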

Other observations

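Single members of some lists not described above passed the threshold for RA in control cells. Of 14 germline genes 1 rose, Taf7l, a germline paralog of a TFIID subunit (1.21 ± 0.21), and 2 rose when adjusted over the list alone (list adjusted p = 0.0546). In shLOXL2 cells 2 rose, Taf7l and Slc25a31, an adenine nucleotide carrier gene (adjusted p = 0.00545), and 3 when adjusted over the list alone. Of 17 interferon response genes 2 fell, the RNA sensor gene Ddx58 (-1.91 ± 0.12) and Bst2 (-0.74 ± 0.14), and 1 rose, the same counts as adjusted over the list alone. Camera did not call the list (adjusted p = 0.539), while fry did (adjusted p = 0.00412). Of 17 hypoxia response genes the glucose transporter gene Slc2a1 rose by 0.74 ± 0.12, while Pdk1 fell by 0.80 ± 0.15 and Ndrg1 fell by 1.04 ± 0.21 (2 rose and 3 fell when adjusted over the list alone, list adjusted p = 0.867). The adjusted p of Ndrg1 was 0.0595 and 0.0586 without replicates 1 and 2 of shCT with RA. Of 18 fibroblast and feeder cell genes only Fbln1, of the extracellular matrix, passed (0.61 ± 0.14), or 2 adjusted over the list alone. Its adjusted p was between 0.0726 and 0.142 without any 1 of 5 shCT arrays, all but replicate 1 without RA, and the list had an adjusted p of 0.313 with an estimated correlation.

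No member passed the threshold for RA in shCT in the lists of p53 targets (15 genes, list adjusted p = 0.235), mitotic cell cycle (17 genes, 0.875), TFIID subunits (15 genes, 0.389), cytosolic ribosomal proteins (25 genes, 0.125) and 2-cell-like genes (12 genes, 0.0546). The 4 lysyl oxidase family genes measured were all higher with RA in shCT, led by Loxl1 at 0.49 ± 0.14, and none passed over all genes (1 adjusted over the list alone). That list was called with the preset correlation (adjusted p = 0.0186) and not with an estimated one (adjusted p = 0.115). In shLOXL2 cells the lists of germline, 2-cell-like, epithelial and ribosomal protein genes were called with the preset correlation, and with an estimated one none was (adjusted p = 0.166, 0.418, 0.197 and 0.48).

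Along the axis within groups, 263 of 370 Zfp genes, which encode zinc finger proteins, had a positive loading, and their median was 0.17 against -0.05 for matched lists. Of 30 replication-dependent histone genes 26 had a negative loading, with a median of -0.38.

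A correlation of the knockdown changes without and with RA would be one sign of a shared knockdown effect. The exact one-sided p of 0.16 leaves chance open as its source, and the highest other relabelling reached r = 0.616.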
